A study of Drosophila melanogaster with 12 samples.

How the data were processed

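Anti-FLAG ChIP-seq was done in S2 cells whose endogenous Phaser or Saft gene carried the tag, with fixation in 1% formaldehyde for 10 min and sonication to 200 to 1000 bp, per the labels' protocols. Sequencing was single-read and the 2 replicates of each clone are described as biological, per the labels. The submitters' processing notes name Trim Galore 0.6.2, Bowtie 1.2.2, bedtools 2.27.1 and MACS2 2.1.2.1 and the genome build dm3, without their order or settings. Names of heterochromatic scaffolds in the lists (2LHet, 2RHet, 3LHet and 3RHet) belong to that build.

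The deposited files were 6 peak lists in narrowPeak format, 1 for each ChIP library and not pooled, and the 6 input libraries entered no list of their own. The deposited fold enrichment is a linear ratio of ChIP pileup over background at the summit, as MACS2 writes it in this format. The deposited −log10 p and −log10 q are those of the authors' peak caller at the summit. The lowest −log10 q of each list lay between 1.30 and 1.44, and a q of 0.05 corresponds to 1.30. The deposited score was the whole part of 10 times −log10 q in 100% of peaks and was not used. Fold and −log10 q were used to describe, rank and filter peaks within a list. Depth was not given in the sources used here, so intervals on shares are 95% Wilson intervals over regions and cover counting error only. No rows were identical between any pair of lists, and no interval was repeated within a list.

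Comparisons were made on the main arms (2L, 2R, 3L, 3R, 4 and X). Peaks were shared if they overlapped by 1 bp or more. The reproducible set of a clone held the stretches common to both replicates, and the Saft regions were the stretches common to the sets of both clones. Overlap was compared with 1000 random placements on the same arm, one-sided, with each arm taken to end at the last peak of any list. P-values over regions treat regions as independent, and they compare these lists rather than the spread between cultures. Peak numbers were compared by exact permutation of log2 numbers per library. Sharing in the strongest and weakest quintile was compared by Fisher's exact test, and the odds ratios of the factors by Zelen's exact test, added after a normal approximation because of small counts. Arms were compared with 100000 permutations of the factor over regions. P-values were adjusted by Benjamini-Hochberg over 5 overlap tests and over 2 strength tests. Tests, sets and alternatives were fixed before the data were examined, apart from those said to be chosen later. The rule for named regions was the 10 best of each factor by the mean within-list rank of −log10 q, and the 5 best shared regions by the sum of those ranks. Values of a region are those of the strongest peak that overlaps it in each list, averaged over the 2 Phaser or 4 Saft lists. The quintiles were not cut on averages but on −log10 q in replicate 1 of Phaser or replicate 1 of Saft clone 9C. Where that replicate was left out, replicate 2 of the clone was used.

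The table of genes at hand is of Release 6, another build, so no coordinates were joined to it. The planned promoter shares, gene lists and sequence words were therefore not run. No list of an untagged line was used here.

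The ChIP reads and the background behind each peak were recovered from the authors' fold and −log10 p, a step chosen after the data were seen. MACS2 adds 1 to pileup and background before taking their ratio, and its p is a Poisson tail, so the 2 values fix both. Background was required to be a window count (a whole number, or a multiple of 150 over 10000) or the floor of the library, and the pileup a whole number of reads times one factor per library. With a tolerance of 0.03 reads, 100% of peaks came out whole in each list, against 6.03% to 6.39% with a wrong factor. That factor lay between 0.289 and 0.435. The processing notes do not state whether the input libraries were the controls, so the recovered background is that of the peak caller. A factor below 1 is what MACS2 gives where ChIP reads are scaled to a smaller control. The recovered counts describe peak summits and not library depth.

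On simulated lists of 896 regions, 0%, 15% and 50% planted overlap with Phaser gave measured shares of 3.31%, 17.9% and 51.7%, and was called in 5%, 100% and 100% of 40 runs. Unplanted regions were placed at random as in the test itself, so the 5% does not cover clustering of real peaks. The exact test of equal odds ratios called 3.8% of 1000 runs without a difference. The arm test called 3.5% of 200 runs without a difference, and the strength test 2.5% of 200 runs without a trend. Read recovery returned the planted number in 100% of 1200 simulated peaks. Alternatives were reciprocal overlap of 50%, summits within 100 bp, −log10 q of 10 or more, the 1000 strongest peaks, all sequences, random shifts of 20 to 200 kb, other rankings and sets, and each replicate left out in turn. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.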

Results

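Binding of Phaser (CG7372) and Saft (CG11247), which the labels call transcription factors, was mapped by ChIP-seq in Drosophila melanogaster S2 cells, an embryo-derived line. Each endogenous gene carried a FLAG tag joined to an auxin-inducible degron, and anti-FLAG antibody was used on cells that were left undepleted. The 12 samples were 6 ChIP libraries and 6 input libraries. Phaser was mapped in clone 8D and Saft in clones 9C and 4H, with 2 biological replicates of each clone. The 6 deposited peak lists, 1 for each ChIP library, are compared here, in dm3 coordinates. The read depth of each library is unknown, so the number of peaks is the size given for each list. The lists held 5299 and 3988 peaks for Phaser, 1389 and 1515 for Saft clone 9C, and 1212 and 1265 for Saft clone 4H. Peaks are named by position alone, since no dm3 gene annotation was used here.

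Phaser lists held more peaks than Saft lists, and the Saft lists had higher upper quartiles of fold enrichment. On the main chromosome arms the Phaser libraries held 4641 ± 925 peaks (SD, n = 2) and the Saft libraries 1340 ± 134 (SD, n = 4). The geometric mean was 3.44 times higher for Phaser (exact permutation test, two-sided, p = 0.0667, n = 2 against 4). Every Phaser list was longer than every Saft list, and 0.0667 is the smallest p that the 15 assignments allow. The upper quartile of the authors' fold enrichment was 6.51 and 5.72 in the Phaser lists. It was 9.47 and 8.03 in Saft clone 9C and 9.25 and 10.5 in clone 4H, while the medians of all 6 lists lay between 3.47 and 4.50. The highest values overlapped, with 18.9 and 16.3 for Phaser and 16.9 to 20.6 for Saft, and the quartiles come from lists of unlike length. In every list the highest summit held 283 to 290 recovered ChIP reads, so alike highest values do not show alike strength. Peaks of 250 recovered reads or more made up 18.6% to 21.5% of the Saft lists and 1.98% and 2.77% of the Phaser lists. Read depth was not given in the sources used here, and peak number moves with it.

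**Figure D1:**
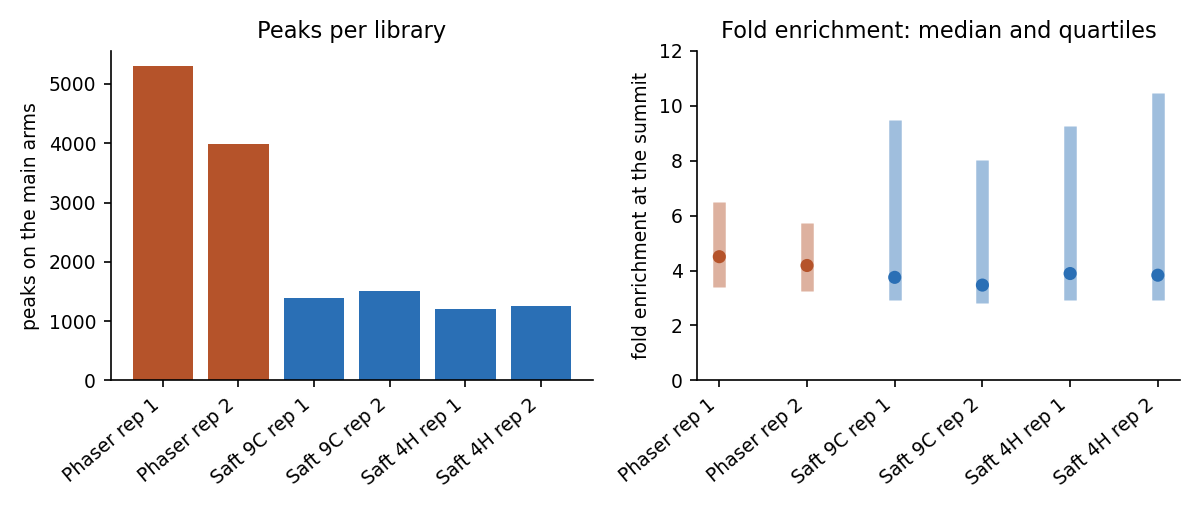
Left, peaks on the main arms in each of the 6 ChIP libraries (bars, number of peaks). Right, the authors' fold enrichment at the peak summit, with the median of each list as a point and the lower to upper quartile as a thick line; the Saft upper quartiles (8.03 to 10.5) lie above those of Phaser (5.72 and 6.51).

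Most sites of each factor were found in both cultures of a clone. Of the 3987 peaks in the shorter Phaser list, 3858 (96.8%, 95% Wilson interval 96.2 to 97.3) overlapped a peak of the other list, 23.7 times the 4.09% given by random placement. Of the longer list, 70.2% of the 5295 peaks overlapped the shorter one. The stretches common to both lists gave 3898 Phaser regions with a median width of 332 bp, and covered 1605 kb. For Saft, 1133 of 1383 peaks (81.9%, 79.8 to 83.9) were found in both replicates of clone 9C, 53.1 times chance. In clone 4H 949 of 1207 peaks (78.6%, 76.2 to 80.8) were found in both, 61 times chance. With only peaks of −log10 q of 10 or more, the shares were 96.7%, 94.5% and 94.3% in the same order. Each of these overlaps had a permutation p of 0.001 (one-sided, adjusted p = 0.001 over 5 overlap tests), the smallest that 1000 placements can give. The placements treat regions as independent, and they measure overlap of lists rather than spread between cultures.

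The 2 Saft clones marked largely the same places. Of the 959 regions reproducible in clone 4H, 871 (90.8%, 88.8 to 92.5) overlapped a reproducible region of clone 9C, 75.1 times the 1.21% given by random placement (permutation p = 0.001, one-sided, the smallest possible). The stretches common to both clones formed 896 Saft regions with a median width of 418 bp, and covered 552 kb. Peaks of one clone that touched no peak of the other were weak. They made up 21% and 25.3% of the 9C lists and 14.2% and 14.8% of the 4H lists, and their −log10 q did not exceed 14.0, whereas the lists reached 95.3 to 115. Clone 9C held 1445 ± 87.7 peaks and clone 4H 1235 ± 38.9 (SD, n = 2 each), a ratio of 1.17 (exact permutation test, two-sided, p = 0.333). With 2 libraries on each side, 0.333 is the smallest p that can be reached.

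**Figure D2:**
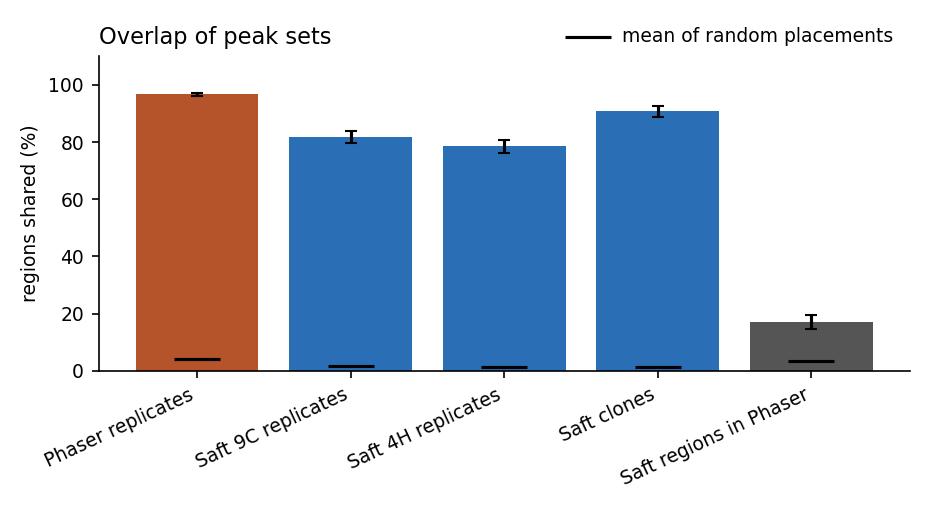
Share of regions (%) that overlapped by 1 bp or more between replicates, between the Saft clones, and of Saft regions with Phaser regions. Bars carry 95% Wilson intervals and black marks give the mean of 1000 random placements; replicates and clones shared 78.6% to 96.8%, and Saft regions shared 17% with Phaser.

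The factors were compared to ask whether they occupy the same places in the genome. Most regions belonged to one factor alone. Of the 896 Saft regions, 152 (17%, 14.6 to 19.6) overlapped a Phaser region, 5.02 times the 3.38% given by random placement (permutation p = 0.001, one-sided, the smallest possible). The same 152 places made up 3.90% (3.34 to 4.55) of the 3898 Phaser regions. By the definition of the sets, each was present in all 6 lists. The excess over chance came from Saft regions of lower −log10 q. Among Saft regions with −log10 q under 30 in replicate 1 of clone 9C, 142 of 360 (39.4%, 34.5 to 44.6) were shared, 17.8 times chance. Among those of 30 or more, 10 of 536 (1.87%, 1.02 to 3.4) were shared, below the 4.12% of random placements (permutation p = 0.002 for so low a count, one-sided). The value of 30 was chosen after the data were seen. Limited to the 1000 strongest peaks of each list, the overlap was 1.23% and no longer above chance (permutation p = 0.455), and with −log10 q of 10 or more it was 3.72% (permutation p = 0.030). Without Phaser replicate 2, whose list is the shorter, it was 28.3%.

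Sharing was lower in the strongest than in the weakest quintile for both factors. Quintiles were cut by −log10 q in 1 library of each factor, replicate 1 of Phaser and replicate 1 of Saft clone 9C. In the weakest to the strongest quintile of Phaser regions, 8.34%, 7.82%, 4.24%, 3.21% and 1.54% overlapped a reproducible region of either Saft clone. That is the wider definition fixed for this test and takes in 196 Phaser regions, where the regions of both clones take in 152. Against the latter the shares were 5.39%, 7.31%, 3.47%, 2.69% and 0.641%. The odds of sharing in the strongest quintile were 0.172 of those in the weakest (95% interval 0.0919 to 0.320, Fisher's exact test, two-sided, p = 1.32e-10, adjusted p = 1.32e-10 over 2 tests). In Saft the shares overlapping a Phaser region were 20.7%, 58.7%, 3.91%, 1.12% and 0.556%, so that sharing rose before it fell, and the second-weakest quintile, with −log10 q of 8.03 to 29.4, held 105 of the 152 shared regions. The odds ratio of the strongest to the weakest Saft quintile was 0.0214 (0.00291 to 0.158, Fisher's exact test, two-sided, p = 1.82e-11, adjusted p = 3.64e-11). It rests on a single shared region in the strongest quintile, and became 0.00774 without Phaser replicate 2, 0.0448 without replicate 1 of clone 9C and 0.0861 without replicate 1 of clone 4H. A difference between the factors in these odds ratios did not hold. The log odds ratios differed by 2.08 as defined (exact test of equal odds ratios, two-sided, p = 0.0281). With Phaser also counted against the regions of both clones they differed by 1.66 (exact test, p = 0.199), and as defined but without replicate 1 of clone 4H by 0.532 (exact test, p = 0.726). As defined, the difference was 1.47 (exact test, p = 0.0504) without replicate 1 of clone 9C and 3.2 (exact test, p = 1.84e-08) without Phaser replicate 2. In clone 9C, shared Saft regions had a median fold enrichment of 4.49 and 4.35 in the 2 replicates, against 9.98 and 9.07 for regions outside Phaser. In Phaser the medians were 4.84 and 3.64 for shared regions and 5.64 and 4.31 for the others.

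**Figure D3:**
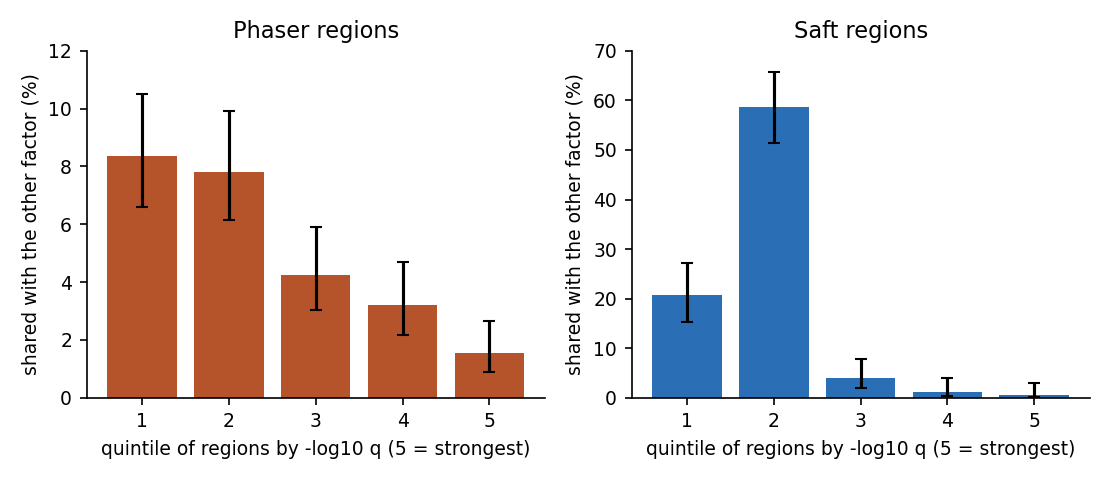
Share (%) of Phaser regions that overlapped a reproducible region of either Saft clone (left) and of Saft regions, those common to both clones, that overlapped a Phaser region (right), by quintile of −log10 q from weakest (1) to strongest (5). Quintiles used replicate 1 of Phaser and replicate 1 of Saft clone 9C. Bars carry 95% Wilson intervals and the vertical scales differ; sharing went from 8.34% to 1.54% in Phaser and peaked at 58.7% in the second Saft quintile.

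The 10 strongest regions of each factor by −log10 q were mostly on the X. With 10 regions per factor, they are too few to show whether the factors lay apart there. Of all Phaser regions only 3.90% were shared, and random placement of Saft regions with −log10 q of 30 or more gave 4.12%. All 10 of the Saft regions with the best mean rank by −log10 q were on the X, and none overlapped a Phaser region. The first 4 lay at 14772781 to 14773716 (17.6-fold ± 1.73, SD, n = 4), 13212310 to 13213047 (17.7-fold ± 2.43), 16511347 to 16512459 (17.3-fold ± 1.56) and 17145972 to 17146761 (17.5-fold ± 1.56). The next lay at 17127762 to 17128299, 669003 to 670052, 13037557 to 13038210, 18822302 to 18822876, 11046939 to 11048136 and 17123477 to 17124661, with mean enrichments down to 16.1-fold. Among the 10 strongest Phaser regions by −log10 q, 7 were on the X and none overlapped a Saft region. They were led by X, 10536051 to 10536871 (17.3-fold ± 1.49, SD, n = 2), X, 2106684 to 2108518 (17.1-fold ± 1.48) and X, 3146019 to 3147078 (16.5-fold ± 2.62). The others on the X lay at 1279416 to 1281634, 10397813 to 10399111, 10146496 to 10147304 and 15453221 to 15454141. The remaining Phaser regions were on 2R at 18876684 to 18877679 (15.2-fold ± 1.83) and 14898056 to 14898757 (14.5-fold ± 1.11), and on 3R at 16329184 to 16329841 (14.1-fold ± 0.793). By recovered ChIP reads, the mean ranks of these regions ran from 3.25 to 218.75 for Saft and from 6 to 144 for Phaser, and only 8 of the 100 best regions of each factor by reads were on the X. Fold enrichment and −log10 q are both taken against the background of the peak caller. That background was at its floor, the lowest value of the list, under 59.1% to 68.1% of X peaks and 0.573% to 2.09% of autosomal peaks. The X to autosome ratios of median background, 0.636 to 0.665, are thus set by the floor and do not measure the X background itself.

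The 5 shared regions with the best summed ranks come from a sum that favours regions strong in Phaser, since ranks range more widely in its longer lists, and they do not show which factor is stronger at shared places. Over all 152 shared regions the median enrichments were 4.84 and 3.64 in the Phaser lists and 4.08 to 4.49 in the Saft lists. At X, 6963033 to 6963228, enrichment was 14.3-fold ± 2.19 for Phaser (SD, n = 2) and 4.40-fold ± 1.1 for Saft (SD, n = 4). At 3R, 20508380 to 20508687, it was 8.24-fold ± 1.49 and 3.55-fold ± 0.266, and at X, 13830869 to 13831103, it was 9.19-fold ± 0.922 and 3.67-fold ± 0.617. At 3R, 2982962 to 2983361, it was 7.88-fold ± 2.18 and 5.86-fold ± 1.92. At X, 4411553 to 4411936, it was 8.52-fold ± 2.17 and 8.89-fold ± 1.64. Enrichments of different lists are set side by side as the authors' values, with no test between them.

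Both factors were spread over the large arms. Phaser regions were densest on 3R, with 42.5 per Mb, followed by 3L (35.3), 2R (33.1), 2L (32.2) and X (21.6). Saft regions were densest on 3L, with 8.94 per Mb, followed by 3R (8.63), 2R (8.22), 2L (6.68) and X (5.64). The X held 12.3% (11.3 to 13.3) of Phaser and 14.0% (11.8 to 16.4) of Saft regions, and 18.8% of the span covered. The peak caller's background was at its floor under most X peaks and few autosomal ones, so detection may differ between them. Neither factor had a region on chromosome 4. Over regions not shared between the factors, the distribution over arms did not differ past the threshold (Cramér's V = 0.0383, permutation test over 3746 Phaser and 744 Saft regions, p = 0.160). Regions are not independent replicates of a factor, so this p is a description of the lists.

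**Figure D4:**
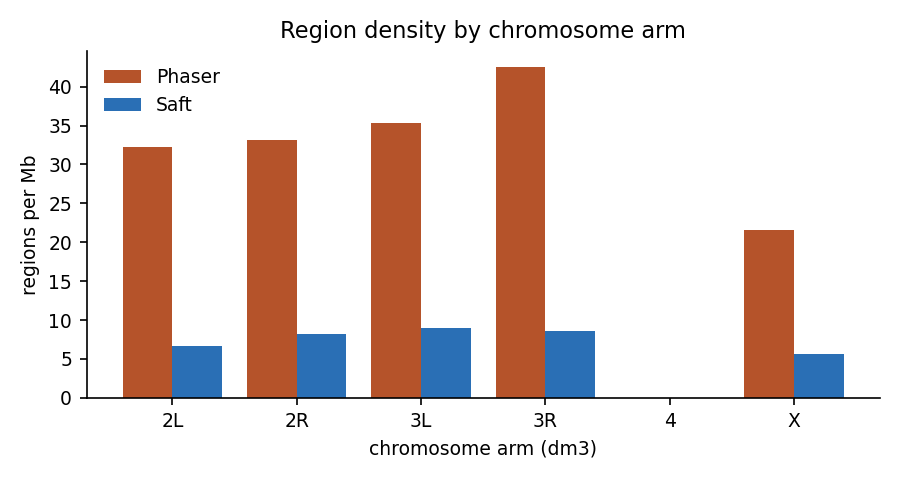
Density of Phaser and Saft regions (regions per Mb) on each chromosome arm, dm3. Phaser ranged from 21.6 on the X to 42.5 on 3R and Saft from 5.64 on the X to 8.94 on 3L; chromosome 4 had none.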

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

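The difference in sharing between the strongest and the weakest quintile was compared between the factors by tests that were not planned and were run after the values were seen, and the difference did not hold. The log odds ratio of the strongest to the weakest quintile was higher in Phaser than in Saft by 2.08 (exact test of equal odds ratios, two-sided, p = 0.0281), where a normal approximation, run first, gave p = 0.0515. Phaser was counted there against the regions of either Saft clone, and Saft regions were those common to both. With both factors counted against the other's set the difference was 1.66 (exact test, p = 0.199). Without replicate 1 of clone 4H it was 0.532 (exact test, p = 0.726) as defined first and 0.177 (exact test, p = 1) with like sets. Without Phaser replicate 2 it was 3.2 (exact test, p = 1.84e-08) and 3.66 (exact test, p = 1.60e-08), and without replicate 1 of clone 9C 1.47 (exact test, p = 0.0504) and 0.855 (exact test, p = 0.437). The Saft value rests on 1 shared region of 180 in its strongest quintile.

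Peaks outside the main arms, which entered only the alternatives that used all sequences, were listed where a library had more than the 3 that a count of 0 allows, since no control list was used. That bar is low, because each count is far below 0.05 of its list, the share that the q limit allows to be false. Heterochromatic scaffolds held 4 peaks in Phaser replicate 1, 6 and 8 in replicates 1 and 2 of Saft clone 9C, and 5 in replicate 1 of clone 4H. Phaser replicate 2 held 1 and replicate 2 of clone 4H held 3. All were weak, with fold enrichment of 2.09 to 4.12 and −log10 q of 1.78 to 8.93. One place on 2LHet, between 32630 and 32971, had a peak in all 6 lists, with fold enrichment of 2.30 to 3.35. No explanation was tested for these peaks.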

How the results depend on the processing

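The 10 main results were recomputed under 92 alternatives, and 90 kept their side of the threshold. Those 90 also kept their direction where there is one, and the arm comparison has none. The exceptions both concern the overlap of Saft with Phaser. It lost its excess over chance among the 1000 strongest peaks of each list (1.23%, permutation p = 0.455), and turned below chance in Saft regions with −log10 q of 30 or more (1.87%, 0.453 times chance), a limit chosen after seeing the data, as were rankings by recovered reads and the comparison with the second-lowest quintile. Both alternatives keep strong peaks, and regions under 30 were shared at 39.4%, so the change goes with peak strength. Leaving out each replicate in turn moved this overlap between 15.9% and 28.3%, the Saft clone overlap between 76.1% and 93.7%, and the ratio of Phaser to Saft peak numbers between 2.99 and 3.97. Saft odds ratios then ranged from 0.00774 to 0.0861 and Phaser ones from 0.147 to 0.215. The tests of peak number cannot pass 0.05 at this size, so they say nothing about stability. Replicate numbers are shared between clones, but the correlations of same-numbered deviations were 0.0292, 0.0389 and 0.0283, and the samples share only a number. With a replicate block the ratio of 3.44 had an exact p of 0.111 and the ratio of 1.17 an exact p of 0.5, and no call changed. Counting each row changed nothing, since no interval was repeated. Of 40 ranks of named regions by fold enrichment or recovered reads, 26 moved by more than the spread between libraries. Neither of these rankings of named regions was planned. Promoter shares, gene lists and sequence words, with their alternatives, were not run for want of dm3 annotation and sequence. Unknown depth limits every comparison of peak numbers.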

Other observations

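Tests of dense stretches, of the X share of shared regions, of median reads on the X, of summit distance, of an untagged line and of weak peaks beside strong ones were chosen after the results were seen. The X share by reads was set against that by −log10 q, and the joining of regions within 1 kb was added, after first results on these patterns. Nor was the X share of the 100 best regions among the planned tests.

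The Saft windows of 100 kb with most regions held 15 on 2R between 16452555 and 16536145, 14 on 2R between 14084253 and 14160507, and 12 on 2L between 8882612 and 8923103, whereas no window held more than 9 in any of 1000 random placements. Their median enrichments were 10.1-fold in each of the 2R stretches and 4.63-fold in that of 2L. Joined where they lay within 1 kb, these regions made 6, 7 and 8 sites. With such joining everywhere, the 896 regions made 756 sites, and random placement of those sites gave at most 8 in a window, so that none of these stretches exceeds the highest placement once pieces are joined. The densest window of joined sites held 10, on 2L between 4572876 and 4634407 (permutation p = 0.001, one-sided, the smallest possible). For Phaser a window on 2L between 4670132 and 4752431 and one on 3R between 26779046 and 26874836 each held 18 regions, as many as the highest of the random placements, but only 11 and 12 sites once joined, where placements of joined sites gave a median maximum of 12. The densest Phaser window of joined sites held 16, on 3R between 15713751 and 15807008, against at most 19 in the placements (permutation p = 0.007, one-sided).

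Merging the 4 Saft lists gave 1971 regions. Of these, 788 were in all 4 lists, with a median of 10.2 for the highest fold in any list, and 692 were in a single list, with a median of 2.81. Phaser overlapped 19.5% of the former and 5.20% of the latter, so sharing was not highest at the least reproducible places. The 152 regions shared with Phaser lay on the X in 21.7% of cases (15.9 to 28.9), against 12.4% (10.2 to 14.9) of the 744 other Saft regions (Fisher's exact test, two-sided, p = 0.00438). Within Saft regions with −log10 q under 30 the shares were 21.8% and 11.0% (Fisher's exact test, two-sided, p = 0.00678). Peaks on chromosome 4 were found only in Saft clone 4H, 2 and 3 in its replicates, with 1 place, from 1290937 to 1291368, in both.

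The X was over-represented among the strongest Saft regions, with 35 of the 100 best by −log10 q against 11.3% of the other 796 (Fisher's exact test, one-sided, p = 9.31e-09). Those 100 include the 10 named Saft regions, all on the X, so this p is not independent of what was already seen. Ranked by recovered ChIP reads, 8 of the best 100 lay on the X (95% Wilson interval 4.11% to 15%), against 14.7% of the others (Fisher's exact test, one-sided, p = 0.981), which argues against more recorded reads on the X as the source of the pattern. Phaser regions showed the same excess, with 26 of 100 by −log10 q (11.9% of the others) and 8 of 100 by reads, so the pattern is not particular to Saft. Median reads on the X minus those on the autosomes were −39.25 in Saft (permutation p = 0.0419) and −29.25 in Phaser (permutation p = 1.00e-05) over all called regions. Among regions of 100 reads or more the differences were −8.75 in Saft (permutation p = 0.481) and −5 in Phaser (permutation p = 0.313). That cut is on the value being compared, so these tests cannot show which regions carry the difference. It kept 77 of 125 X regions and 565 of 771 autosomal ones in Saft. In Phaser it kept 167 of 478 and 2085 of 3420. A larger share of X regions thus had fewer than 100 reads, and why was not tested. A candidate explanation is that reads capped near the 283 to 290 of the highest summits (1 read per position and strand would allow 300 with an extension of 150 bp), over an X background that the peak caller mostly held at its floor, lifted X regions to the top; stronger occupancy beyond such a cap stays open, and no biological explanation was tested.

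Of the 152 Saft regions shared with Phaser, 142 had −log10 q under 30, though the weakest quintile (20.7% shared) came after the second-weakest (58.7%). Summits lay within 100 bp in 81.6% of the 152 shared regions, while random summits in the same peaks gave 42.6% on average and 53.3% at most. The peaks were those of replicate 1 of Phaser and of Saft clone 9C, and a region counted if any overlapping pair was that close. Those draws kept the touching peaks in place, so they cannot decide whether wide peaks touched by chance. They also spread summits evenly over each peak, with no allowance for summits that lie near peak centres. Random placement of regions argues against chance contact, since 39.4% of Saft regions under 30 were shared, against 2.21% in the placements. With sharing defined by summits at most 100 bp apart, 11.4% of 667 Saft regions were shared, 18.2 times chance. A higher background, as the peak caller took it, is argued against too, because at shared autosomal Saft regions it was 0.982 of that at the others; the notes do not state that the input was the control behind it. Sites that any anti-FLAG ChIP would recover, and sites that both factors visit weakly, cannot be told apart, since no list of an untagged line was used. Presence of the 152 regions in all 6 lists follows from how the sets were defined and favours neither.

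Weak Saft peaks (−log10 q under 10) lay beside strong ones (30 or more). Of 2990 weak peaks in the 4 Saft lists, 683 (22.8%) lay within 1 kb of a strong peak, 16.5 times chance. Between 2 and 10 kb the count was 234, 1.86 times chance (permutation p = 0.001, one-sided, the smallest that 1000 placements can give). The ratio of these folds was 8.89, past the 3 set for shoulders, so that shoulders split off a strong site may account for much of the excess at close range, and clusters of separate sites could add to it farther out; no biological explanation was tested beyond that. Both Phaser lists showed the pattern less sharply, with 4.95 and 5.46 times chance within 1 kb, 1.73 and 2.03 times between 2 and 10 kb, and ratios of 2.87 and 2.69, below that limit, which leaves shoulders undecided in Phaser.

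The hypothesis that Saft regions outside Phaser regions still lie in the same neighbourhoods was not borne out. Of the 744 such regions 34.3% lay within 10 kb of a Phaser region. Among randomly placed regions that likewise overlapped no Phaser region the share was 39.3% (one-sided permutation p = 0.995).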
